A study of Mus musculus with 4 samples.

How the data were processed

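Poly(A)-selected RNA from Hepa1-6 cells, a mouse hepatoma line, was sequenced in 4 libraries. Per the labels' protocols, cells were transduced with lentivirus, kept under 4 μg/ml puromycin for 3 weeks, and lysed in Trizol, and 10 μg of total RNA entered each preparation. The Control group (n = 2) received a scrambled shRNA and the Chd1KD group (n = 2) an shRNA against Chd1. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate transductions, so p-values measure only the spread between these libraries, which may be technical.

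The authors deposited RPKM values (reads scaled to transcript length and to the number of mapped reads) for 30582 rows, each a RefSeq transcript, per the file headers. The submitters' processing notes name TopHat 1.4.1, Cufflinks 1.3.0 and the mm10 build. The annotation release, strand setting, filters and scaling are not given in the sources used here. The 4 single-library tables held the same 30582 values as the matching columns of the series table, so the series table was used throughout. Columns were assigned by the sample descriptions.

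Transcripts were named through the NCBI table for GRCm38.p6, the assembly behind mm10, which matched 29999 rows, and through GENCODE M21, which matched a further 184. The remaining 399 rows kept their accession and made up 0.304% of the summed RPKM. RPKM was summed over the transcripts of each gene, giving 23521 genes, of which 4221 had more than 1 transcript. This summing was settled when the rows proved to be transcripts. A total of 577 rows were further genomic copies of a transcript and were summed with it, so multi-copy genes carry extra uncertainty. Coordinates are from the NCBI table, 1-based.

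RPKM values carry no read counts, so no count model was used. Sequencing depth is unknown and no counting interval or detection floor is given. Relative depth was read from 1148 transcripts at low RPKM in all libraries. The commonest ratio placed the other libraries at 1.01 times the depth of Control replicate 1, but only 70 to 73 of the 1148 values carried it in each library, so it is a weak estimate. An exact 0 in these tables need not mean absence, because 10 genes with a mean of at least 5 RPKM were at 0 in 1 to 3 of the libraries. Such genes are given library by library.

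Genes with a mean RPKM of at least 1 over the 4 libraries (10209 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a mean-variance trend, no covariate and no replicate block. Benjamini-Hochberg adjusted p under 0.05 was a call. Log2 fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes, and ratios are of group mean RPKM without a pseudocount. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333 and was not used. On simulated data with the same 10209 genes and fitted spread, 200 changed genes per draw and 10 draws per fold, the test recovered 62.5% of genes changed 1.5-fold and 91.3% of genes changed 2-fold. False calls were 4.5% and 6.1% of all calls. The noise was normal and independent between genes and libraries, without the deviations that real genes share. These rates therefore do not give the share of false calls in the real data.

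A total of 39 gene lists with 1082 entries were fixed before the data were examined. They covered chromatin factors, liver and lipid metabolism, the cell cycle, stress and signalling programmes, and markers of other liver cell types. An older symbol served for 7 entries and 5 entries were not matched. The 35 lists with at least 5 tested genes were tested with camera (limma, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation, and fry, were alternatives. With an estimated correlation, camera uses the residual degrees of freedom, which are few in 4 libraries, so it had little power to call a list. Members changed "adjusted over the list alone" are counted beside those changed over all genes. That count does not control error over the 39 lists.

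Named genes followed a rule fixed in advance. It took the CHD family, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap (unnamed loci skipped), and from each described list up to 4 changed members with the smallest p, or up to 2 where none changed. Actb, Gapdh and Tbp were level checks. Prim2, Ccne1, Ccne2, Igf2bp1, Gpc1, Lamb1, Vim, Trp53, Stab1, Aldh1a1, Nolc1 and Rps27 fell outside the rule and were named after their values were seen. Some genes that the rule takes are not reported here. Alternatives covered the pseudocount, the filter, scaling, the variance model, the replicate number as a block, the thresholds and each library left out. Leaving out genes listed at 0, using each gene's most abundant transcript, and removing a GC and length trend were added after the data were seen. The replicate numbers carried no stated pairing. Figures were drawn with matplotlib 3.10.9.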

Results

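The data comprised gene-level RPKM from 2 Control and 2 Chd1KD libraries of Hepa1-6 cells. Summed RPKM ranged from 459381 in Chd1KD replicate 2 to 484490 in Control replicate 1. Between 10161 and 10209 genes reached 1 RPKM in a library, and the 10 most abundant genes held 7.10% to 7.23% of the summed RPKM. Log2(RPKM + 1) values of tested genes correlated across genes at r = 0.992 between the Control libraries and r = 0.995 between the Chd1KD libraries, against 0.990 to 0.994 for the 4 pairs that crossed groups. Control replicate 2 correlated more closely with Chd1KD replicate 2 (r = 0.994) than with Control replicate 1. The median absolute log2 difference was 0.095 within Control and 0.068 within Chd1KD, against 0.097 to 0.119 for the pairs that crossed groups. Sequencing depth was unknown.

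The single comparison of the design asked which mRNAs differ when Chd1, an ATP-dependent chromatin remodeler that binds methylated histone H3, is lowered in a hepatoma line. Chd1 mRNA fell by about a factor of 2. The gene lies on chromosome 17 from 15704967 to 15772612 (mm10) and is protein-coding. It measured 21.4 and 22.5 RPKM in the Control libraries and 10.4 and 11.3 RPKM in the Chd1KD libraries. The means were 21.96 ± 0.75 and 10.8 ± 0.67 RPKM (SD, n = 2 each), a ratio of 0.49, and the log2 fold change was -0.96 with an SE of 0.07 (limma, adjusted p = 0.012). Without the filter on low values the fold was -0.96 with an adjusted p of 0.25.

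Of the 8 tested CHD remodelers, Chd1 was the only one to pass over all genes. Adjusted over the list alone, Chd1, Chd3 and Chd1l fell and Chd2 and Chd9 rose. The list had a median log2 fold change of 0.03 and a mean of -0.09, the median turned negative without Control replicate 1 and under both other filters, and camera did not call the list (adjusted p = 0.84). Chd3, a NuRD complex ATPase, had a mean of 62.6 ± 2.8 RPKM in Control and 51.6 ± 1.2 in Chd1KD (limma, adjusted p = 0.11 over all genes). Chd2, the closest relative of Chd1, had 8.51 ± 0.53 and 10.7 ± 0.17 RPKM, a ratio of 1.26 (limma, adjusted p = 0.11 over all genes). Chd1l had a ratio of 0.78 and Chd9 a ratio of 1.41. Chd4 had a ratio of 1.07, Chd8 of 1.06 and Chd6 of 0.99, none of these 3 passed on either count, and the sign of Chd6 turned under quantile normalization. Chd5 stayed at or below 0.022 RPKM in every library. Actb, Gapdh and Tbp had ratios of 0.95, 0.87 and 0.98 and did not pass the test.

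Across 10209 genes, 47 changed (limma, adjusted p under 0.05). Of these, 28 were higher and 19 lower in Chd1KD, and the groups did not overlap for any of the 47. Across all tested genes the groups did not overlap for 51.8%, where chance gives 33.3%. An unadjusted p under 0.05 was reached by 1890 genes (739 higher, 1151 lower), where 510 would be reached by chance. Over all tested genes 43.5% had a positive fold change and the median log2 fold change was -0.02, the baseline for the gene lists below. On the log2(RPKM + 1) scale 5 of the 47 changed at least 2-fold, Dmkn, Pglyrp1, Lgals2 and Anxa8 downward and Il18 upward.

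The largest fall among called genes was in Dmkn. This gene, which encodes the skin protein dermokine, measured 3.07 and 6.92 RPKM in Control and 0.30 and 0.042 RPKM in Chd1KD. Pglyrp1, a peptidoglycan recognition protein, fell from 9.05 ± 2.92 to 1.74 ± 0.53 RPKM. Lgals2, a galectin, fell to 0.36 of Control (log2 fold change -1.33, SE 0.12) and Anxa8, an annexin, to 0.35 (-1.09, SE 0.09). Tff1, a secreted trefoil peptide, fell from 25.3 ± 0.47 to 15.5 ± 0.16 RPKM. Slco2a1, a prostaglandin transporter, fell to 0.66 of Control.

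Skp2, the F-box protein that targets the CDK inhibitor p27 for degradation, fell from 36.04 ± 1.2 to 19.8 ± 0.012 RPKM (log2 fold change -0.83, SE 0.06, limma, adjusted p = 0.012). Timeless, a replication fork protection factor, fell to 0.63 of Control, and Cenpv, a centromere-associated protein, fell to 0.62. Rdh10, a retinol dehydrogenase, fell from 22.7 ± 0.76 to 13.1 ± 0.85 RPKM.

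The largest rise was in Il18, which encodes a cytokine of the interleukin-1 family. It measured 0.79 ± 0.0073 RPKM in Control and 2.89 ± 0.29 RPKM in Chd1KD, a ratio of 3.66 (log2 fold change 1.12, SE 0.11, limma, adjusted p = 0.017). Btg3, an antiproliferative member of the BTG/Tob family, rose from 26.4 ± 0.95 to 49.1 ± 1.3 RPKM, a ratio of 1.86 (log2 fold change 0.87, SE 0.06, limma, adjusted p = 0.012). Cpox, an enzyme of heme synthesis, rose 1.80-fold, and Ptgr1, a prostaglandin reductase, 1.58-fold. Aldh1a7, an aldehyde dehydrogenase, rose 1.88-fold, an uncertain value because its reads may be split with its close and more abundant paralog Aldh1a1 (251.8 ± 3.8 RPKM in Control and 287.8 ± 6.3 in Chd1KD). Psmb6, a catalytic subunit of the proteasome, rose from 109.1 ± 10.6 to 172.0 ± 8.1 RPKM, and the lysosomal membrane protein Lamp1 rose from 144.6 ± 9.6 to 213.1 ± 11.9 RPKM. Tmem63b, a membrane channel protein, rose 1.62-fold. Pmp22, Rasgrp3, Col22a1 and Arrdc4 rose 1.61-fold, 1.598-fold, 1.58-fold and 1.57-fold, with adjusted p from 0.043 to 0.049 (limma).

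**Figure D1:**
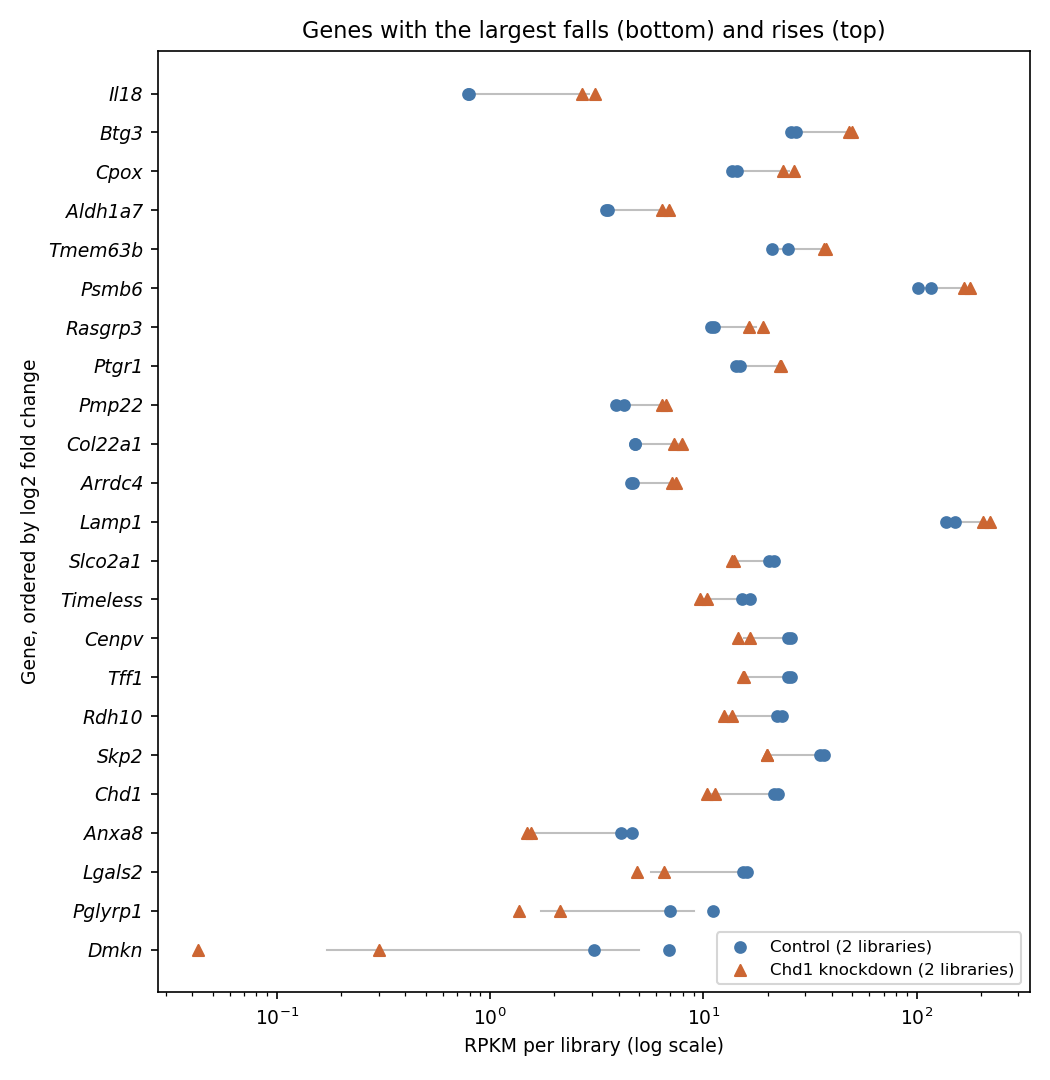
RPKM per library (horizontal log axis) for 11 of the 12 genes with the largest falls and the 12 with the largest rises, ordered by log2 fold change; circles are the 2 Control and triangles the 2 Chd1KD libraries, and grey lines join the group means. By the rule that picked them, both Chd1KD libraries lie on the same side of both Control libraries in all 23 genes drawn. Chd1 is at 21.4 and 22.5 against 10.4 and 11.3 RPKM.

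Of the 24 genes with the largest falls and rises, 9 overlap another annotated gene, and 5 overlap a protein-coding one (Il18, Tmem63b, Lgals2, Anxa8 and Skp2). The strand setting of the quantification is not given, so reads of such partners cannot be excluded. The number of calls was 0 without a filter on low values (limma, with 2153 genes at an unadjusted p under 0.05), 6 without a variance trend, 12 with the most abundant transcript of each gene, 92 with a robust trend, 75 with exact zeros left out, and 68 (48 higher, 20 lower) with a GC and length trend removed. It was 140 without Control replicate 1, 236 without Control replicate 2, 49 without Chd1KD replicate 1 and 122 without Chd1KD replicate 2.

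Most tested genes of DNA replication were lower in Chd1KD, but whether the list was called depended on the test used. Of 37 tested genes of S phase and replication, 32 had a negative fold change, with a median log2 fold change of -0.17. None passed over all genes (limma), where 22 had an unadjusted p under 0.05. Adjusted over the list alone, 14 fell and 3 rose. The falls included Pold1, the catalytic subunit of DNA polymerase delta (35.84 and 35.21 RPKM in Control, 28.49 and 27.52 in Chd1KD), the licensing factor Cdt1 (48.9 to 38.6 RPKM), the polymerase alpha subunit Pola2 (34.4 to 27.6 RPKM) and the helicase subunit Mcm3 (126.0 to 100.8 RPKM), each at 0.79 to 0.80 of Control. The 3 rises were in Prim2, Ccne1 and Ccne2, a primase subunit and the 2 E-type cyclins, at 1.247, 1.17 and 1.18 times Control. Between the Control libraries the list median differed by -0.12 (replicate 2 minus replicate 1). This exceeded in size the smallest of the 4 pairs between groups (-0.11). Camera with an estimated correlation called 0 of the 35 lists, most at the same adjusted p of 0.91. That test also uses the few residual degrees of freedom of 4 libraries, so it could hardly call any list. Its 0 calls alone do not show that correlation between members undoes a call. The replication list was called by camera with the preset correlation (adjusted p = 3.0e-06). It lost its call with fry (adjusted p = 0.44) and in camera with an estimated correlation (unadjusted p = 0.31, adjusted p = 0.91 with an estimated correlation). It kept its call in each of the 4 fits that left out 1 library, with medians from -0.23 to -0.13.

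Of 35 tested genes of G2 and mitosis, 31 had a negative fold change, with a median of -0.08 against -0.02 over all tested genes. None passed over all genes (limma), and 4 fell adjusted over the list alone. An unadjusted p under 0.05 was reached by 5 of the 35, a smaller share than the 1890 of all 10209 tested genes. The 4 that fell were Nusap1 and Ndc80, of the spindle and kinetochore, and the mitotic kinases Plk1 and Aurkb, at 0.81, 0.79, 0.85 and 0.84 of Control. Camera called the list lower (adjusted p = 0.012), not with an estimated correlation (adjusted p = 0.91 with an estimated correlation). The call was lost without Control replicate 1 (median -0.05, camera, adjusted p = 0.27) and without Chd1KD replicate 2 (median -0.07, camera, adjusted p = 0.17), and the median was -0.12 without Control replicate 2. Between the Control libraries the median differed by -0.10 (replicate 2 minus replicate 1), more in size than 2 of the 4 pairs between groups (-0.01 and -0.06).

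Of 27 tested targets of the tumour suppressor p53, 21 had a positive fold change, with a median of 0.13, and none passed over all genes or adjusted over the list alone (limma). Among all 10209 tested genes 1890 reached an unadjusted p under 0.05. Of these 27 targets 7 did, of which 6 were higher and 1 was lower. The lower one was Trp53, the p53 gene itself, named after its values were seen, with 171.6 ± 8.8 RPKM in Control and 145.3 ± 5.4 in Chd1KD. Plk2, a polo-like kinase, had 102.9 ± 5.2 RPKM in Control and 128.3 ± 5.9 in Chd1KD, and Ccng1, cyclin G1, had 135.2 ± 17.8 and 181.1 ± 16.5 RPKM. Camera called the list higher (adjusted p = 0.0017), not with an estimated correlation (adjusted p = 0.91 with an estimated correlation). The call was lost without Control replicate 2 (median 0.03, camera, adjusted p = 0.19) and without Chd1KD replicate 1 (median 0.02, camera, adjusted p = 0.056), and the median was 0.20 without Chd1KD replicate 2.

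The remaining list called by camera held cholangiocyte markers, genes of biliary epithelium, and 3 of its 5 tested members (Spp1, Sox9 and Epcam) also stood in the fetal liver list. All 5 tested members had negative fold changes, with a median of -0.36 (camera, adjusted p = 0.012, and adjusted p = 0.91 with an estimated correlation). The estimated correlation of this list was -0.16, under the preset 0.01 (camera, unadjusted p = 0.082 with an estimated correlation). Correlation between its members therefore does not account for the lost call. Without a filter on low values the adjusted p was 0.076. Adjusted over the list alone, Spp1 (osteopontin), Krt7 (a simple-epithelium keratin), Sox9 (a progenitor transcription factor) and Epcam (an adhesion molecule) fell to 0.77, 0.64, 0.79 and 0.69 of Control. Sox9 moved from a log2 fold change of -0.32 to -0.19 without Chd1KD replicate 1. None passed over all genes (limma), where 4 had an unadjusted p under 0.05. Of matched markers of other liver cell types, 14 of 15 for macrophages, 12 of 14 for endothelium, 14 of 15 for fibroblasts and stellate cells and 10 of 10 for lymphocytes had a mean under 1 RPKM. Of these, 9, 8, 7 and 9 were listed at 0 in all 4 libraries, which need not mean absence. The exceptions were Cd14 (7.8 to 7.0 RPKM), Egfl7 (3.3 to 1.9 RPKM, a fall adjusted over the list alone that moved from -0.56 to -0.30 on the log2 scale without Control replicate 1), Stab1 (1.6 to 1.9 RPKM) and Dcn. Dcn, a matrix proteoglycan, was abundant at 408.0 ± 31.4 RPKM in Control and 389.5 ± 5.3 in Chd1KD (limma, adjusted p = 0.65).

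**Figure D2:**
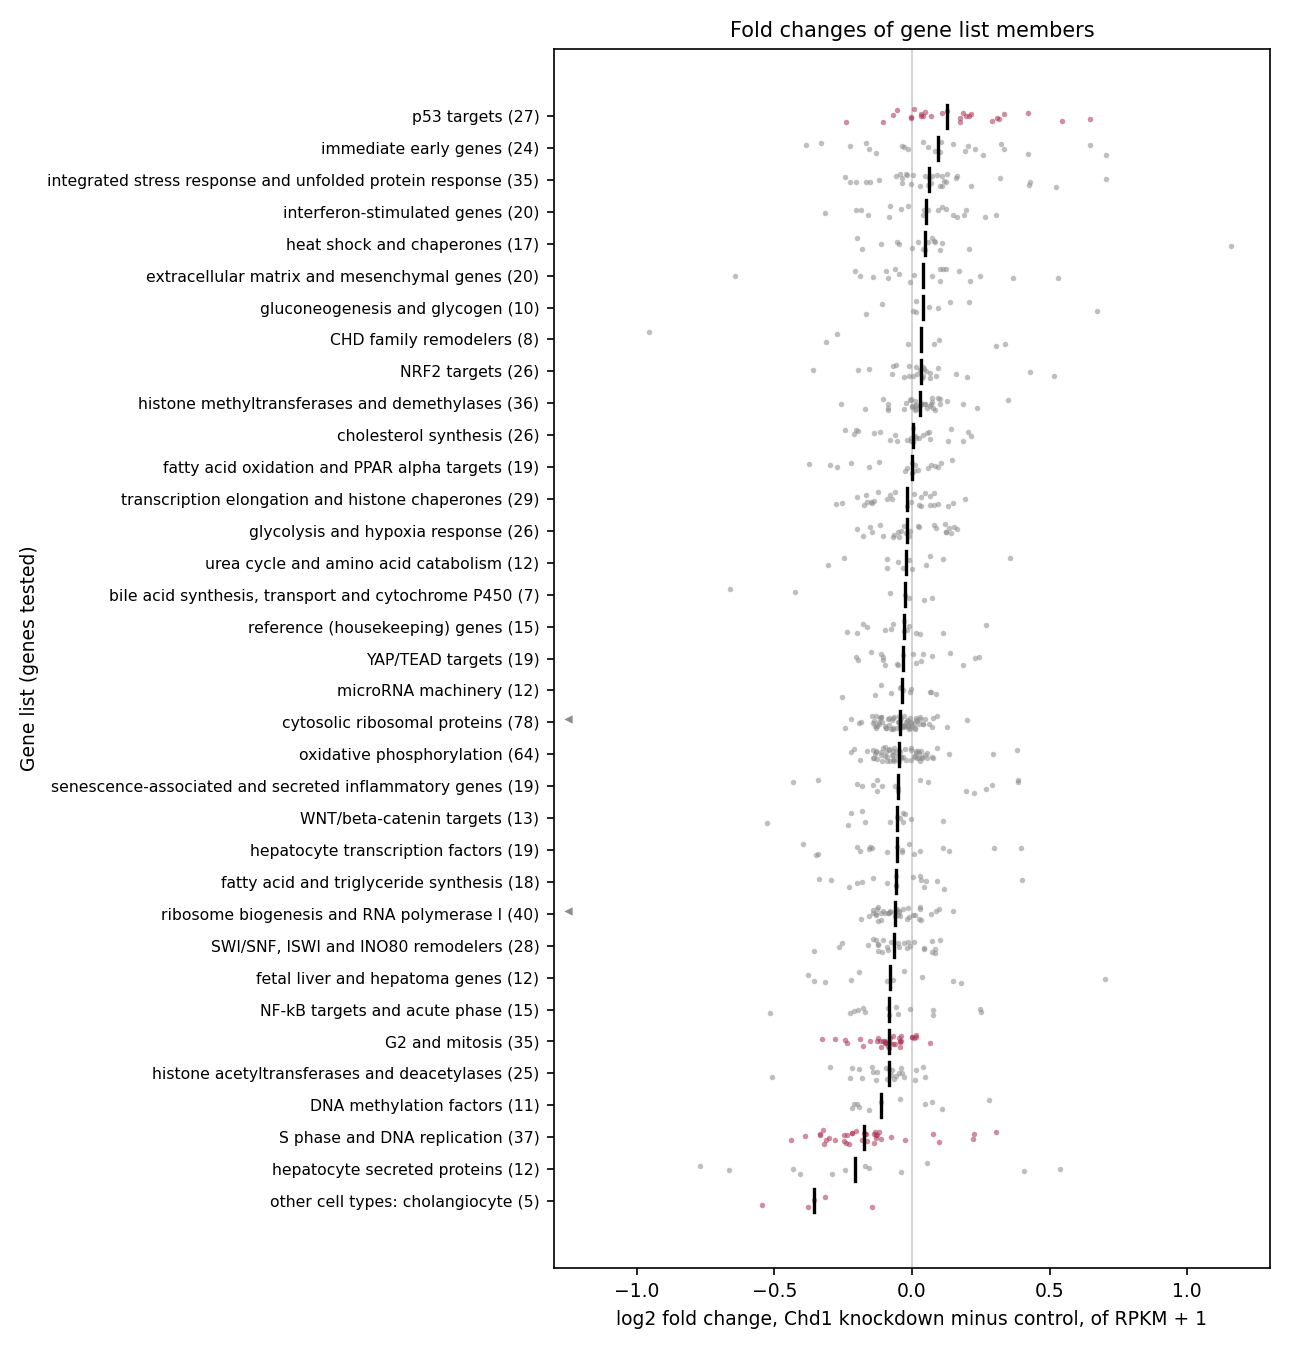
Log2 fold change (Chd1KD minus Control, of RPKM + 1) of every tested member of the 35 lists tested; each point is a gene, vertical bars are list medians, coloured lists had a camera adjusted p under 0.05 and arrowheads mark 2 genes beyond the axis (Rps27 and Nolc1). The replication list has its median at -0.17 and the p53 target list at 0.13.

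The other 31 lists were not called by camera, with adjusted p from 0.076 to 0.92. Some of them were called by camera when 1 library was left out. These were the acetyltransferase, hepatocyte secreted protein, hepatocyte transcription factor, bile acid, heat shock and WNT lists without Control replicate 1, and the histone methylation, ribosomal protein, ribosome biogenesis and oxidative phosphorylation lists without Control replicate 2. The stress response list was called without Chd1KD replicate 1, and the acetyltransferase, hepatocyte secreted protein and immediate early lists without Chd1KD replicate 2. Median and mean had opposite signs for cholesterol synthesis (0.0034 and -0.0065) and senescence (-0.05 and 0.0012). Glycolysis, amino acid catabolism and YAP/TEAD targets had negative medians and means while camera, which compares a list with the other genes, pointed upward. The medians of these 5 lists lay near 0 and each changed sign when 1 of the libraries was left out (Chd1KD replicate 2 for senescence, glycolysis and YAP/TEAD targets, Control replicate 2 for amino acid catabolism, and either Control replicate 2 or Chd1KD replicate 1 for cholesterol synthesis). Members at an unadjusted p under 0.05 (limma) are given as "unadjusted" for lists where none passed on either count. Among all tested genes 1890 of 10209 were at that level, so such counts alone do not mark a list. For the same reason a short list can readily hold members that pass only when adjusted over the list alone. Among chromatin factors, none of 28 SWI/SNF, ISWI and INO80 genes changed on either count (3 unadjusted; Smarcb1 0.77 and Hells 0.83 of Control), and none of 36 histone methyltransferases and demethylases did (4 unadjusted; Kdm5b 1.29 and Ezh2 0.83). Of 25 histone acetyltransferases and deacetylases, 21 had negative fold changes (camera, adjusted p = 0.076) and only Hdac10 fell adjusted over the list alone, from 3.25 ± 0.11 to 1.99 ± 0.079 RPKM. Of 11 DNA methylation factors, Mbd1 rose to 1.22 and Uhrf1 fell to 0.86 of Control adjusted over the list alone. Neither the 29 elongation factors and histone chaperones (5 unadjusted; Nelfcd 0.82, Chaf1b 0.83) nor the 12 microRNA machinery genes (1 unadjusted; Ago2 0.83, Tnrc6c 0.89) held a changed member.

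Of 12 tested secreted proteins of hepatocytes, none passed over all genes, and 4 fell adjusted over the list alone. These were Cp (ceruloplasmin), Apob (the structural protein of very-low-density lipoprotein), Rbp4 (the plasma retinol carrier) and Apoe, at 0.47, 0.72, 0.76 and 0.57 of Control. The log2 fold change of Rbp4 was -0.41, and -0.25 without Chd1KD replicate 1; that of Apoe was -0.77, and -0.41 without Control replicate 2. The list had a median of -0.21 (camera, adjusted p = 0.17) and was called without Control replicate 1 (median -0.37, adjusted p = 0.00061) and without Chd1KD replicate 2 (median -0.40, adjusted p = 0.00042), but the median was -0.09 without Chd1KD replicate 1. Apoe varied between the Control libraries, at 1222 and 2023 RPKM, against 784.4 and 1080 RPKM in Chd1KD. Afp, the fetal liver protein alpha-fetoprotein, rose from 34.8 ± 6.9 to 56.7 ± 2.2 RPKM adjusted over the list alone (limma, adjusted p = 0.077 over all genes). In that list of 12 tested fetal and hepatoma genes, Igf2bp1 also rose and Spp1, Igf2bp3, Sox9, Gpc1 and Epcam fell. Of the 19 tested hepatocyte transcription factors none changed (6 unadjusted), with Hnf4a at 48.6 ± 3.2 and 38.1 ± 3.7 RPKM and Nr5a2 at 1.46 times Control. Cyp1a1 and Cyp7b1, a xenobiotic and an oxysterol hydroxylase, fell to 0.62 and 0.64 of Control adjusted over the list alone, of 7 tested bile acid and cytochrome P450 genes.

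Metabolic lists held few changed members, and none passed over all genes. None of 26 cholesterol synthesis genes (6 unadjusted; Ebp 0.86 of Control) or 18 fatty acid and triglyceride synthesis genes (3 unadjusted; Lpin1 1.44, Dgat1 0.84) changed. Adjusted over the list alone, Acaa1a, a peroxisomal thiolase, fell to 0.74 among 19 fatty acid oxidation genes. Pcx, pyruvate carboxylase, rose 1.79-fold among 10 gluconeogenesis genes. Fah, the last enzyme of tyrosine breakdown, rose 1.33-fold among 12 amino acid catabolism genes. No member changed among 26 glycolysis and hypoxia genes (4 unadjusted; Gapdh 0.87, Eno1 0.89), 64 oxidative phosphorylation genes (6 unadjusted; Cox4i1 1.23, Ndufs5 1.31), 78 ribosomal protein genes (6 unadjusted; Rps12 0.85, Rps20 0.86) or 40 ribosome biogenesis genes (1 unadjusted; Gar1 0.91, Taf1c 0.86). Nolc1, in the last list, was at 119.3 RPKM in Control replicate 1 and listed at 0 in the other libraries.

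Members of the stress and signalling lists changed only when adjusted over the list alone. Atf3 and Chac1, of the integrated stress response, rose 1.76-fold and 1.73-fold among 35 genes of that list (camera, adjusted p = 0.076). Cryab, a small heat shock protein, rose 2.80-fold among 17 chaperones, from 2.95 and 2.24 RPKM in Control to 9.40 and 5.13 in Chd1KD. Its log2 fold change of 1.16 ran from 0.78 to 1.54 without 1 library. Gsr, glutathione reductase, fell to 0.78 of Control among 26 NRF2 targets. Among 24 immediate early genes Atf3 and Fosl2 rose while Fosl1 and Klf4 fell. Il1rn, the interleukin-1 receptor antagonist, fell to 0.66 among 15 NF-kB and acute phase genes. Lgr5, Ccnd1 and Axin2 fell to 0.67, 0.85 and 0.86 among 13 WNT targets. Among 20 matrix and mesenchymal genes Sparc, Nid1, Thbs1 and Lamb1 rose and Tgfbi and Vim fell adjusted over the list alone. Without Control replicate 1 the log2 fold change of Thbs1 moved from 0.53 to 0.28 and that of Nid1 from 0.37 to 0.24. No member changed among 20 interferon-stimulated genes (2 unadjusted; Adar 0.74, Irf1 0.86), 19 senescence and secreted inflammatory genes (5 unadjusted; Cxcl5 0.73, Timp1 1.32), 19 YAP/TEAD targets (1 unadjusted; Amotl1 1.24, Arhgef17 0.81) or 15 reference genes (3 unadjusted; Gapdh 0.87).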

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

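Tests with exact zeros left out, with the most abundant transcript and with a GC and length trend removed were chosen after the data were seen; the other settings were fixed in advance. Chd1 stayed lower under every setting run, at -1.01 to -0.90 without 1 library, and missed the threshold only without a low-value filter (-0.96, adjusted p = 0.25), where 0 genes were called, 0 higher and 0 lower (limma, 2153 at an unadjusted p under 0.05). Counts of changed, higher and lower genes, against 47, 28 and 19, were 71 changed and 45 higher at a mean RPKM of at least 5, 6, 3 and 3 without a variance trend, and 92, 52 and 40 with a robust trend. They were 75, 45 and 30 with exact zeros left out, 12, 5 and 7 with the most abundant transcript, and 205, 100 and 105 at an adjusted p under 0.1. They were 5, 1 and 4 at 2-fold or more, and 48 were higher with the GC and length trend removed. The pseudocounts and scalings gave 45 or 47 calls. Leaving out 1 library gave 49 to 236 changed genes, 19 to 119 higher and 30 to 117 lower, and 4 to 9 called lists (9 without Control replicate 1, 7 without Control replicate 2, 6 without Chd1KD replicate 2); the group left with 1 library was assumed to vary like the other. With the replicate number as a block, 325 genes were called, 158 higher and 167 lower, and 6 lists; same-numbered libraries deviated together at a correlation of 0.22 over genes, but 2 numbers with no stated meaning do not pair the libraries. With an estimated correlation camera called 0 of the 35 lists, and most shared an adjusted p of 0.91. That test has few residual degrees of freedom in 4 libraries, so few or no calls were likely at any correlation. The 4 called lists then had unadjusted p of 0.31 (replication), 0.47 (G2 and mitosis), 0.46 (p53 targets) and 0.082 (cholangiocyte markers). With fry, 1 list was called, the SWI/SNF, ISWI and INO80 list, lower (adjusted p = 0.016). The 23 largest risers and fallers besides Chd1 kept their direction in all 365 fits that tested them and passed the threshold in 297. These 23 were picked as called genes whose groups did not overlap. Their direction could therefore turn only under the scalings, the most abundant transcript or the GC and length trend. Among the other named genes, signs turned for some that did not pass. These were Chd6 (0.013 with quantile normalization, -0.095 to 0.069 without 1 library), Actb (-0.16 to 0.0049), Tbp (-0.11 to 0.053), Cd14 (-0.26 to 0.0028) and Dcn (-0.14 to 0.014). Medians of lists were less stable, as 18 of the 35 changed sign under some setting, 15 of them without 1 library, though 0 of the 4 called lists did. Medians without 1 library ran from -0.016 to 0.061 for the CHD family, -0.024 to 0.026 for cholesterol synthesis and -0.080 to 0.00091 for senescence. The unknown depth limits what can be said of genes near 1 RPKM. The causes of these shifts were not tested. The stricter filter left fewer genes to test, 7705 against 10209.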

Other observations

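The split of the libraries and both tests on exact zeros were chosen after the values were seen. The other tests below had their predictions written first, although removal of the GC and length trend was itself added after the data were seen.

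The Hepa1-6 libraries of both groups expressed part of the hepatocyte programme. Of 41 matched hepatocyte secreted proteins, 29 had a mean under 1 RPKM and 22 were listed at 0 in all 4 libraries, among them Ttr, Fga and Serpina1a. An exact 0 need not mean absence. Apoe and Rbp4 were abundant, at 1622 ± 566 and 404.0 ± 36.8 RPKM in Control (SD, n = 2). The regulator Hnf4a was at 48.6 ± 3.2 RPKM. Alb varied between the Control libraries, at 18.6 and 55.6 RPKM, against 42.2 and 53.02 RPKM in Chd1KD. The most abundant genes included Sprr1a, a cornified envelope precursor of stratified epithelium, which ranked 9 of all genes with 2473 ± 378 RPKM in Control and 3060 ± 280 in Chd1KD. Krt18 was at 740.3 ± 3.8 and 621.3 ± 0.58 RPKM. Krt19, a biliary keratin under the low-value filter and so not tested, was at 1.13 and 1.04 RPKM in Control and at 0.085 and 0 in Chd1KD. Sprr1a, Krt18 and Krt19 were picked after their values were seen.

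With 4 libraries there are 3 splits into 2 and 2, too few for a share under 0.05. The real split called 47 genes and the highest other split called 1.

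The replication list had a negative median and the p53 target list a positive one in Chd1KD. Both camera calls were lost with an estimated correlation (adjusted p = 0.91 with an estimated correlation for each), a test with little power in 4 libraries. Both were also lost with fry (adjusted p = 0.44 and 0.70), and no p53 target passed on its own. A single scaling error or a trend with expression level is argued against as the whole cause. The list medians lay at percentiles 0 (replication) and 100 (p53 targets) of 10000 random lists matched on mean expression. Camera, which compares a list with the other genes, had already called both lists, so extreme percentiles were likely. Random lists also lack the correlation between members (estimated at 0.58 and 0.87), so the percentiles do not measure chance. GC content and transcript length as the whole cause are argued against too. With that trend removed the replication median was -0.16, against -0.17 before. The list remained called by camera with the preset correlation (adjusted p = 9.1e-08, against 3.0e-06 before the removal). Camera with an estimated correlation, which had not called the list before the removal (adjusted p = 0.91 with an estimated correlation), was not run after it. Variation of growth state between cultures irrespective of group may account for part of the pattern, because the replication median differed by 0.12 in size between the 2 Control libraries, above the smallest of the 4 differences between groups (0.11). For p53 targets the Control libraries differed by more (-0.22, replicate 2 minus replicate 1) than the groups did (0.13), and 1 of the 4 pairs between groups went the other way (-0.02, Chd1KD replicate 2 minus Control replicate 1); a response to Chd1 loss remains open beside it, and more independent cultures would be needed.

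Among genes with a mean of at least 5 RPKM, 10 were listed at exactly 0 in some library. Xpo1 was at 53.4 and 48.2 RPKM in Control and at 0 and 50.9 in Chd1KD, and Hmga1 at 0 and 169.9 in Control and 193.9 and 183.5 in Chd1KD. A failed estimate in the authors' quantification is a candidate explanation, since 2 of the 10 genes (Nolc1 and Snora15) were at 0 in both libraries of a group and the rest in only part of a group. Loss of expression after knockdown is argued against, as 0 of the 10 were at 0 in both Chd1KD libraries and in neither Control library. Leaving genes with a 0 out of the test raised the number of calls from 47 to 75.

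A hypothesis that genes over long genomic spans were lower in Chd1KD was tested, as Chd1 is known to travel with elongating RNA polymerase. Spearman's rho across 10105 genes, which are not independent replicates, was 0.12 between the log2 fold change and the span, so the predicted negative relation was not seen over the group means. The sign depended on the libraries, as the 4 pairs between groups gave 0.15, 0.060, 0.27 and -0.073. The difference between the 2 Control libraries gave 0.28 and that between the 2 Chd1KD libraries 0.20, both larger than that between groups, so with this spread between libraries the hypothesis stays open.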
